A study of Camellia sinensis with 9 samples.

How the data were processed

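The study sequenced small RNA from root, flower and leaf of Camellia sinensis, the tea plant, with 3 libraries per organ. Per the labels' protocols, total RNA was extracted with TRIzol from untreated plants, and libraries were made with standard Illumina protocols after removal of ribosomal RNA. The labels name the libraries root13, root23, root33, flower1, flower2, flower45, leaf1, leaf23 and leaf41 and do not say whether they came from separate plants, so the p-values measure the spread between these samples only, which may be technical. The trimming, alignment and counting tools and the genome build are not given in the sources used here.

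The deposited table lists 371 named miRNAs with their mature sequences and, per the file headers, 9 count columns, 1 per library, which hold whole numbers and were not normalised by the authors. Beside each count stands a normalised score that the header calls RPTM, which the authors rounded to whole numbers. It equals the count divided by one constant per library, between 2.11 and 2.25. If RPTM means a score per 1e+07 reads, these constants correspond to 21113252 to 22531036 reads per library, but the header does not define the unit. The rounded score was not tested, and RPTM values below are counts divided by these constants, not rounded. One further row names no miRNA, is blank and was left out (1 row, no counts).

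Rows with the same sequence hold the same counts, apart from U or T spelling. The 371 rows hold 341 distinct sequences, and 59 rows share 29 sequences. Reads of such rows cannot be assigned to one locus, so rows of the same sequence are named together where they matter. For 4 of the sequences, the rows stand under 2 family names. A total of 66 rows had 0 reads in all libraries. Names are given without the species prefix csn-. Families follow the number in the name, with miR157 counted under miR156, miR165 under miR166, and miR170 under miR171, which gives 63 families. Genomic positions and target genes were not analysed here.

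The counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test (glmQLFit, glmQLFTest), TMM scaling, filterByExpr by organ, all 9 libraries in 1 fit with organ as the only factor, and Benjamini-Hochberg adjustment at 0.05. The filter kept 155 rows (129 distinct sequences, 99.98% of the counts). Every adjusted p below comes from this test unless another is named. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are after TMM scaling, over all rows, so that a sequence listed in several rows is counted in each. Family counts were summed over rows and tested in the same way, which left 37 families. Where all libraries of an organ had 0 reads, the fold change is given as a bound against 3 counts per library, and 3 counts equalled 1.48 to 7.20 CPM. The depth and these bounds cover counting error only.

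A total of 12 lists of families with a shared role were fixed before the data were examined, as were the tests, the alternatives and the rule for the named miRNAs. The lists were SPL and AP2 phase change, auxin signalling, organ patterning transcription factors, sulfate and phosphate, copper, silencing machinery, NBS-LRR, R2R3-MYB, conserved angiosperm families, questioned families that may be pieces of other RNAs, names with no family number, and animal-numbered families. Lists with at least 3 tested members, 8 in all, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with fry beside it. The named miRNAs were, per comparison, the 10 with the largest change in each direction among those with an adjusted p under 0.05, a mean CPM of at least 10 and no overlap between the libraries of the 2 organs. The 10 most abundant miRNAs per organ, members of a described list and families could be named too. Single values (a ratio and shares) were compared with two-sided exact permutation tests, in which 3 libraries against 3 cannot give a p below 0.1.

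The alternatives were DESeq2 1.42.0 in place of edgeR, other scalings, no low-count filter, a fold of at least 2, only the 6 libraries of a comparison, rows of the same values counted once, and leaving out each library in turn. The authors' divisor as library size, each sequence under a single family, and lists without rows of 2 family names were added after the data were seen. Because the median log2 fold change moved by up to 1.65 with the scaling, each call was also made under 5 scalings: TMM, the DESeq2 size factors, library totals, the authors' divisor, and TMM on each sequence once.

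The steps were tested on simulated counts with the means and library sizes of the real libraries, with 60 of the 155 rows changed, in 10 runs. At a 4-fold change, 29.5% of the changed rows were recovered for root and leaf, 30.6% for flower and leaf, and 27.1% for flower and root. At a 16-fold change the recovered shares were 88.2%, 86.3% and 89.4%. Of the calls, 3.43%, 0.51% and 2.21% were false. The simulated rows were independent, with equal numbers raised and lowered. These shares therefore leave out the uncertainty of the scaling and may not hold for the real data. With 3 libraries per organ and a common biological coefficient of variation of 0.728, most simulated 4-fold changes were not detectable. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.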

Results

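Small RNA was sequenced from root, flower and leaf of the tea plant to characterise miRNAs across its organs. Each organ was represented by 3 libraries. The counts over all rows totalled 643051 to 1208855 in root, 1433624 to 1788497 in flower and 823743 to 882660 in leaf. Counting each sequence once, the totals ranged from 369605 in root13 to 1073284 in flower2. Between 185 and 218 of the 371 listed miRNAs had at least 1 read in a library. If the authors' divisor is the library depth, the distinct miRNA sequences took 4.48% ± 0.48 of the reads in flower, 2.33% ± 0.63 in root and 2.29% ± 0.07 in leaf (SD, n = 3 each). The flower share lay above all root and leaf libraries (exact permutation test, two-sided, p = 0.1 against each, the smallest possible), and root and leaf did not separate (exact p = 0.8).

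Across miRNAs, which are not independent replicates, log2 CPM correlated at r = 0.938 to 0.964 between root libraries and 0.95 to 0.969 between flower libraries. Among the leaf libraries, leaf1 and leaf23 correlated at 0.954, whereas leaf41 reached 0.803 with leaf1 and 0.831 with leaf23, and 0.814 with root33. Counts with and without leaf41 are therefore given beside each comparison with leaf. No 2 libraries agreed within counting noise.

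The miR166 family, which targets class III HD-ZIP transcription factors, led all libraries. It took 67.96% ± 5.53 of the counts in root, 57.0% ± 3.33 in flower and 47.86% ± 4.21 in leaf (SD, n = 3 each). By this share, no library of any organ overlapped with those of another (exact permutation test, two-sided, p = 0.1 for each pair, the smallest possible). After TMM scaling, root overlapped with leaf and with flower, and the family total was called in no pair (adjusted p = 0.0886 for root and leaf, 0.219 for flower and leaf, 0.566 for flower and root). With each sequence counted once the shares were 61.08% ± 6.46 in root, 46.68% ± 3.74 in flower and 40.7% ± 3.89 in leaf, and the log2 difference between flower and root turned from -0.15 to 0.24. The most abundant sequence, shared by miR166a_3p and miR166b_3p (UCGGACCAGGCUUCAUUCCCC), stood at 230600 ± 62080 CPM in root, 219400 ± 34720 in flower and 292300 ± 74860 in leaf per row. It was called in no pair of organs with TMM, and its order among the organs turned with the scaling (root over leaf, log2 -0.34 with TMM and 0.58 with each sequence once). By mean share over all rows, the second family was miR159, whose targets include GAMYB-like factors, in leaf (16.1% ± 7.88) and root (8.19% ± 0.93), and miR171, which targets GRAS genes, in flower (8.71% ± 3.03). With each sequence counted once it was miR167 in leaf (18.9% ± 2.10) and miR171 in both root (9.08% ± 3.05) and flower (14.1% ± 4.56). Over all rows the flower order held in flower1 alone. In flower2 miR159 was second (164353 counts, 133213 for miR171), in flower45 miR167 (156500, with 93508 for miR171) and in leaf41 miR535 (106329, with 63589 for miR159).

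**Figure D1:**
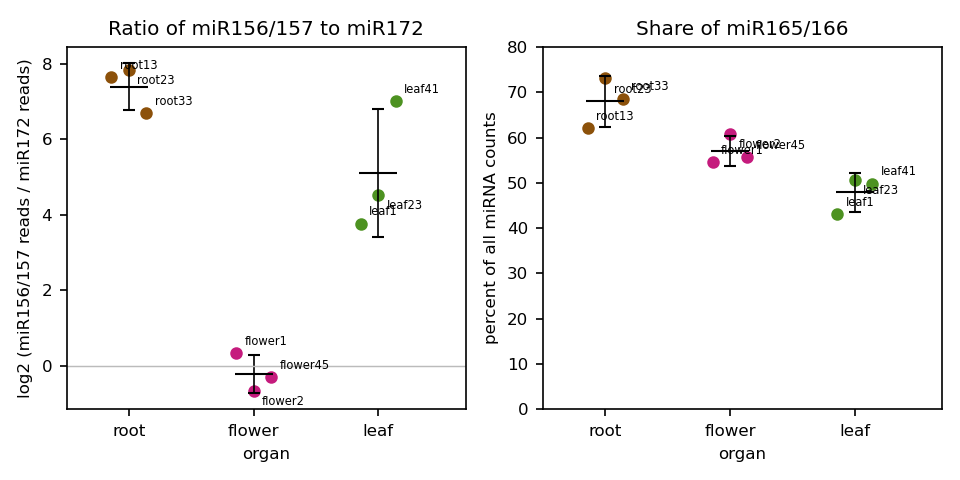
Left, log2 ratio of miR156 to miR172 counts in each library; right, percent of all miRNA counts in the miR166 family. Points are libraries, and bars give the mean and SD of 3 libraries per organ. The flower ratios lie between -0.66 and 0.33, leaf41, with a ratio of 128, lies among the root values, and the miR166 share of all counts is separate for each organ, which the family total after TMM scaling is not.

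By the rule for named miRNAs, the sequences that differed most between root and leaf belonged to the miR171, miR156 and miR167 families, which had members on both sides, and, higher in leaf, to miR398, miR172, miR535 and miR828. MIR171v_3p stood at 2983 ± 542 CPM in root and 16.5 ± 14.5 in leaf (SD, n = 3 each), a 176-fold difference, and its opposite arm MIR171v_5p was 338-fold higher in root (log2 8.40 ± 1.39 SE, adjusted p = 0.00075), a value that rests on 11 counts in leaf41, as leaf1 and leaf23 had 0. MIR167p_3p was 61.7-fold higher in root, and the sequence shared by miR171b_3p and miR171m_3p was 51.4-fold higher. Leaf exceeded root for miR167e_5p, at 94710 ± 48920 CPM in leaf and 1138 ± 558 in root, an 83.2-fold difference, and for miR535a_3p (shared with miR535c2_3p), at 34.4-fold. MIR156j_3p was 229-fold and miR828a_5p 25.4-fold higher in leaf, the latter of a family that targets MYB genes. These differences were found under all 5 scalings and without leaf41.

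At the family level, 4 families were higher in root and 5 in leaf under all 5 scalings. Those higher in root were miR390 (log2 3.57 ± 0.48 SE, adjusted p = 0.000539), which starts the production of small RNAs acting on auxin response factor genes, miR171 (1.79 ± 0.32), miR160 (2.63 ± 0.79), which targets auxin response factor genes directly, and miR397 (3.04 ± 0.82), which targets laccases. Those higher in leaf were miR535 (-2.30 ± 0.25, adjusted p = 0.00016), miR167 (-1.86 ± 0.38), miR828 (-3.75 ± 0.73), miR168 (adjusted p = 0.0301), which targets an Argonaute gene, and miR398 (-7.20 ± 2.25), which targets copper superoxide dismutases. The miR845 total was also called higher in root, but 99.6% of its reads came from rows whose sequence also stands under other families, and its log2 fold change was -0.13 ± 0.68 without them. The miR398 reads in leaf came mostly from leaf41, with 4701 counts against 85 and 256 in the other two.

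By edgeR's quasi-likelihood test, 50 of 155 miRNAs differed, 14 higher and 36 lower in root, and 12 and 18 of these were found under all 5 scalings. The split moved with the scaling: 31 higher and 35 lower with the DESeq2 size factors, 38 and 24 with library totals, 30 and 19 with the authors' divisor, and 28 and 17 with each sequence counted once. Without leaf41 the test called 86 (59 higher, 27 lower), with 29 of the 30 miRNAs of all scalings still called. Without root23 it called 29. The count of families fell from 10 to 1 without root13, where only miR390 was called, to 5 without root23, and to 6 without leaf1 or without leaf23. The miR390 call was made whichever library was left out, and miR171 in all cases except without root13. Those of miR535 and miR167 were lost without root13, root33, flower45 or leaf41, that of miR828 without root13, root33 or flower45, and that of miR397 without root13, root23 or leaf1. The miR160 call was lost without root13, root23, leaf1 or leaf23, that of miR398 without root13, root23, flower2 or leaf23, and that of miR168 in 7 of 9 cases, all except without flower1 or flower2.

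None of the 8 lists differed between root and leaf by camera at an adjusted p of 0.05. At an unadjusted p of 0.05 camera called 1 list, and fry, which asks whether the members move one way, called 3 after adjustment. The nearest by camera was silencing machinery (adjusted p = 0.0896; 0.683 with an estimated correlation; 0.00396 with no low-count filter), of which 6 of 10 tested members were lower in root, 2 of them (miR168a_3p and MIR168g_3p) under all 5 scalings, with the same count adjusted over the list alone. In the SPL and AP2 phase change list, 4 members were higher and 9 lower in root, and 4 and 11 adjusted over the list alone (camera adjusted p = 0.507). The members lower in root were 5 of miR535, 3 of miR172 and MIR156j_3p, and those higher were miR156d_3p, miR156g_3p and the sequence of miR156c_5p and miR156e_5p. The largest list, conserved angiosperm families, had 14 of 140 members higher and 35 lower (camera adjusted p = 0.593). Of the NBS-LRR list, miR482b_5p alone of 3 members was called (log2 -2.09, under 2 of the 5 scalings; camera adjusted p = 0.507).

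**Figure D2:**
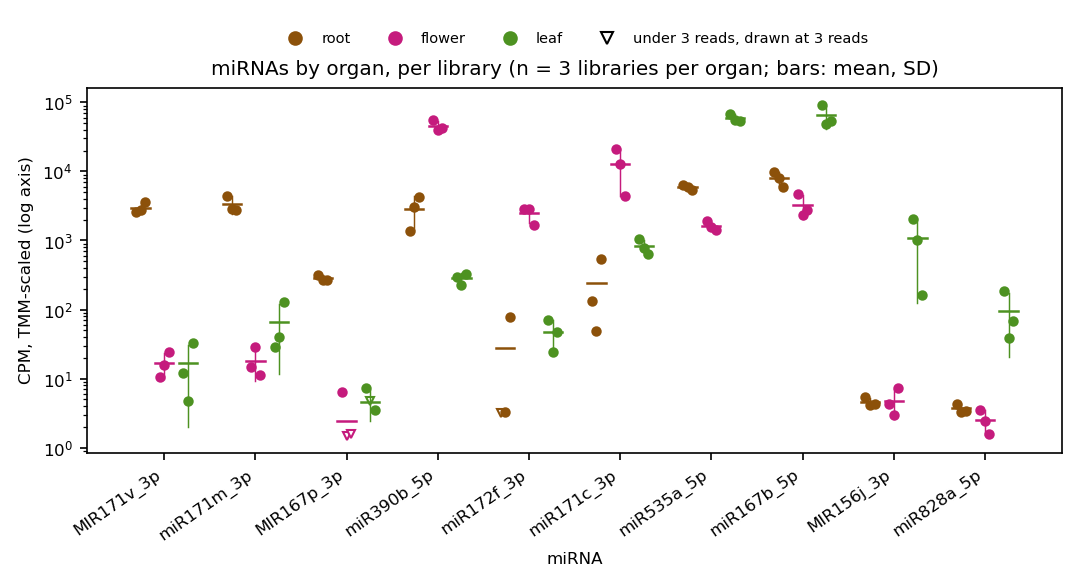
CPM after TMM scaling on a log axis for 10 miRNAs in the 9 libraries, with the mean (bar) and SD (line, where it stays above 1 CPM) of 3 libraries per organ; open triangles mark libraries under 3 reads, drawn at 3 reads. MIR171v_3p, miR171m_3p and MIR167p_3p are highest in root, miR390b_5p, miR172f_3p and miR171c_3p in flower, and the last 4 in leaf.

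Under all 5 scalings, 3 sequences each of miR390 and miR171 were higher in flower than in leaf and 5 of miR535 lower. Of miR172, 3 were higher and 3 lower, and of miR156, 1 was higher and 7 lower. The main miR390 sequence, miR390b_5p (AAGCUCAGGAGGGAUAGCGCC), reached 45820 ± 8349 CPM in flower and 282 ± 50.6 in leaf (SD, n = 3 each), a difference of log2 7.34 ± 0.55 SE (adjusted p = 1.05e-06), and its opposite arm was 69.4-fold higher. miR172f_3p, of a family that targets AP2-like factors, was 52.6-fold higher in flower, MIR171z_5p 17.7-fold and miR171c_3p 15.4-fold. In leaf, the sequence of miR156f_3p and MIR156l_3p was 484-fold higher (1 to 3 counts per library in flower), that of miR156b_5p and MIR156j_5p differed by log2 -7.29 ± 0.72 SE, and the sequence of miR535a_5p and miR535c2_5p was 36.2-fold higher in leaf (log2 -5.18 ± 0.36). The differences of these named sequences were found under all 5 scalings and without leaf41. The call of miR535d_5p (377-fold higher in leaf) was lost without leaf41, in which it stood at 598.8 RPTM (not rounded), against 0.92 and 0.95 in the other leaf libraries. Of the sequences counted above, miR535b_3p, miR156a_5p and MIR156n_3p were also not called without leaf41.

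Among families, miR390 (log2 7.56 ± 0.57 SE, adjusted p = 4.08e-06), miR172 (3.38 ± 0.66) and miR171 (2.66 ± 0.33) were higher in flower, and miR535 (-4.17 ± 0.27, adjusted p = 1.69e-06), miR828 (-4.28 ± 0.74) and the rare miR4376 (-4.27 ± 1.15) higher in leaf, under all 5 scalings. The miR156 total (-1.81 ± 0.46) and miR7122 (-1.88 ± 0.56) were called under 3 of the 5 scalings, with the same sign in all. The miR156 call was also lost without root13, root33, flower2, flower45 or leaf41 in turn (log2 -1.72 to -1.28), and leaf41 held 15651 of its counts against 4972 and 5895 in the other leaf libraries. Leaving out 1 library ended the miR7122 call in 7 of 9 cases, all except without flower1 or leaf23, and that of miR4376 in 6, all except without root23, leaf1 or leaf41, while miR390, miR171 and miR535 were called in all 9, and miR172 and miR828 in all except without flower45. The miR845 total was called higher in flower (2.28 ± 0.47) but stood at -0.86 ± 0.69 without the rows it shares with other families.

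By edgeR's quasi-likelihood test, 68 of 155 miRNAs differed, 20 higher and 48 lower in flower, and 20 and 26 of these were found under all 5 scalings. The split was 28 higher and 33 lower with the DESeq2 size factors, 26 and 38 with library totals, 37 and 26 with the authors' divisor, and 22 and 25 with each sequence once. Without leaf41, 72 were called (42 higher, 30 lower), and 42 of the 46 miRNAs of all scalings were still called. The family count of 9 was 16 without leaf41 and 5 without flower45.

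The SPL and AP2 phase change list was lower in flower by camera (adjusted p = 0.00054), but with an adjusted p = 0.205 with an estimated correlation. Of its 30 tested members, 20 were lower and 4 higher in flower, and 23 and 4 adjusted over the list alone, while 19 and 4 were called under all 5 scalings. The lower members included 9 rows of miR156 and 8 of miR535, families that act on SPL genes, but also miR172a_3p, miR172a_5p and miR172g_5p. Lists take both arms, so 3p rows such as MIR156j_3p, miR156a_3p and miR535a_3p were among them. Some rows share a sequence, such as miR156f_3p and MIR156l_3p. Whether each row acts on SPL genes was not tested. The higher members were miR172f_3p, both arms of MIR172l and miR156h_5p. The auxin signalling list was higher in flower (adjusted p = 0.04; adjusted p = 0.527 with an estimated correlation), with 6 of 22 members higher and 3 lower, the same adjusted over the list alone. Its higher members were 3 rows of miR390 and 3 of miR167. That call was lost without flower1, without leaf1, with no low-count filter, with the authors' divisor, and with rows of the same values counted once. Of the 8 lists, fry called 3. Among those not called by camera (adjusted p = 0.156 to 0.959), silencing machinery had miR403a_3p higher and 4 rows of miR168 lower, with 1 and 5 adjusted over the list alone. The sequence of miR403a_3p is also listed as miR396h_3p, a member of the organ patterning list, so its family is open. Without rows of 2 family names the camera adjusted p of silencing machinery was 0.339 in place of 0.6. Of the miR168 rows, miR168a_5p and MIR168f_5p turned to log2 0.19 with the authors' divisor. Organ patterning transcription factors had 8 members higher and 11 lower, and 8 and 10 adjusted over the list alone, and camera placed the list above the rest (adjusted p = 0.156) although its median log2 fold change was -0.41. That list was called with the DESeq2 size factors (0.0431), with no low-count filter (0.0373), with the authors' divisor (0.0201), and without root13 (0.0144), root23 (0.0262), root33 (0.0193), flower45 (0.0446) or leaf41 (0.0162), but not under the other alternatives (up to 0.599, with an estimated correlation). The conserved families had 19 members higher and 43 lower, and 19 and 46 adjusted over the list alone, the copper list 3 lower, and the sulfate and phosphate list and the NBS-LRR list none called.

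**Figure D3:**
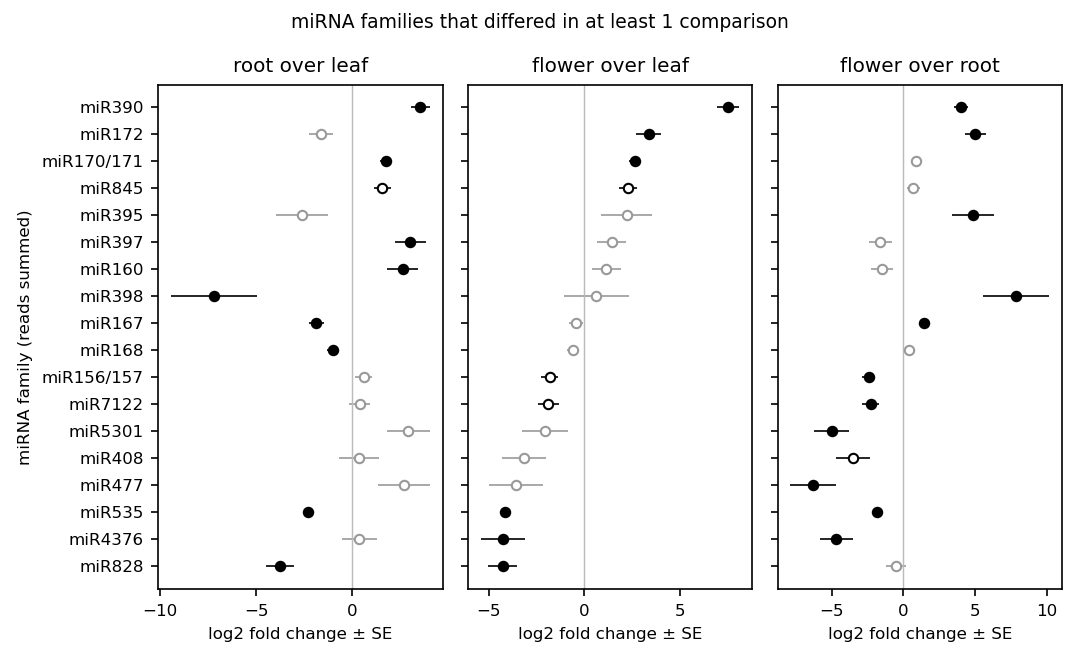
Log2 fold change ± SE (edgeR, n = 3 libraries per organ) of the 18 families called in at least 1 comparison, 1 panel per pair of organs. Black marks adjusted p under 0.05 and grey the rest; filled points were called under all 5 scalings. miR390 is highest in flower and lowest in leaf, miR535 the reverse, and miR845 changes sign in all 3 panels once shared sequences are counted once.

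Between flower and root, sequences of miR172 and miR171 were again among those higher in flower, and sequences of miR156 and others of miR171 among those higher in root. In flower, miR172f_3p was 89.4-fold, MIR171z_5p 70.0-fold and miR171c_3p 52.4-fold higher. The sequence listed as both miR396h_3p and miR403a_3p had 30.5 ± 21.2 CPM in flower (SD, n = 3) and no read in root, at least 11-fold higher against 3 counts per library. In root, the sequence of miR171b_3p and miR171m_3p was 184-fold higher, that of miR156f_3p and MIR156l_3p 531-fold, and miR156d_3p 485-fold (1 or 2 counts per library in flower; log2 -8.92 ± 1.11 SE, adjusted p = 6.23e-05). The sequence of miR156c_5p and miR156e_5p, at 77.9 ± 64.2 CPM in root, had no read in flower, at least 45.4-fold lower. All of these held under all 5 scalings except the last, which was called under 4. With the authors' divisor the low-count filter left it out, so it was not tested there.

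Families higher in flower under all 5 scalings were miR172 (log2 5.01 ± 0.72 SE, adjusted p = 0.000615), miR390 (3.99 ± 0.49), miR398 (7.83 ± 2.31), miR395 (4.83 ± 1.48), which acts in sulfate assimilation, and miR167 (1.44 ± 0.37). Families higher in root were miR535 (-1.87 ± 0.24, adjusted p = 0.000408), miR156 (-2.41 ± 0.47), miR477 (-6.26 ± 1.59), miR5301 (-5.00 ± 1.23), miR4376 (-4.66 ± 1.16) and miR7122 (-2.28 ± 0.57). miR408, with targets among copper proteins, was called lower in flower (-3.50 ± 1.17) under 2 of the 5 scalings. The miR398 counts in flower ran from 231 in flower1 to 9693 in flower45. The miR167 call was lost without root13, root23, root33, flower45 or leaf41 in turn (log2 0.62 to 1.47), the miR408 call without root13, root23, flower1, flower2 or leaf1, and the miR395 call without root13, root23 or flower2. Those of miR398 and miR7122 were each lost in 1 case, without root23 and without root13.

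By edgeR's quasi-likelihood test, 69 of 155 miRNAs differed, 26 higher and 43 lower in flower, and 26 and 37 of these were found under all 5 scalings. The split was 44 higher and 40 lower with the DESeq2 size factors, 26 and 41 with library totals, 47 and 37 with the authors' divisor, and 24 and 31 with each sequence once.

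The SPL and AP2 phase change list was lower in flower than in root by camera (adjusted p = 0.0165; adjusted p = 0.489 with an estimated correlation), with 17 of 30 members lower and 3 higher, and 18 and 3 adjusted over the list alone. It was the only list camera called, where fry called 4. The call was lost without root13, without flower2, and with rows of the same values counted once. In the sulfate and phosphate list, 3 of 6 members were higher in flower, all of miR395 (camera adjusted p = 0.162), with the same count adjusted over the list alone. In the copper list, MIR398c_3p was higher and 2 rows of miR408 lower (camera adjusted p = 0.575). The auxin signalling list had 5 members higher and 3 lower (5 and 2 adjusted over the list alone; adjusted p = 0.115), organ patterning transcription factors 13 and 16 (adjusted p = 0.639), and the conserved families 26 and 39 (adjusted p = 0.331). The R2R3-MYB list had 2 tested members, too few for camera; its miR828a_5p was lower in root and in flower than in leaf.

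Among the 3 organs together, 99 of 155 miRNAs differed by edgeR's F test (80 distinct sequences). A total of 12 rows were higher in root than in each other organ, 12 in flower and 20 in leaf. Of these, 10, 12 and 12 were found under all 5 scalings. Simulated libraries with no difference gave 0 such rows on average for each organ. Their rows were drawn independently with the fitted spread, which leaves out rows that move together and the uncertainty of the scaling. That 0 is thus no chance level for the real rows, and other splits of the real libraries gave up to 8 such rows in all. Independent lists of the observed sizes would give 3.88, 3.35 and 11.1, although comparisons that share libraries also share their chance values. Among those found under all scalings, the root set included 6 rows of miR171, the flower set 3 of miR390, and the leaf set 5 of miR535 and 3 of miR172. Without root23 the total of 44 fell to 28. Low in flower against both other organs were 28 rows, with 9 low in root and 2 in leaf, where independent lists would give 13.3, 6.04 and 1.81. Of these, 16, 4 and 2 were found under all 5 scalings.

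The ratio of miR156 to miR172, families known for opposite roles in phase change, separated flower from the other organs. Its log2 value was -0.20 ± 0.50 in flower, 7.39 ± 0.62 in root and 5.10 ± 1.69 in leaf (SD, n = 3 each), a 39.6-fold lower ratio in flower than in leaf and 193-fold lower than in root. The flower libraries lay below all others (exact permutation test, two-sided, p = 0.1 for both, the smallest possible), whereas root and leaf were not separated (exact p = 0.2). As plain ratios the leaf values were 13.7 in leaf1, 23.1 in leaf23 and 128 in leaf41, the last above the 103 of root33. Between root and leaf the log2 difference was 2.29, and 3.24 without leaf41 and 1.62 without leaf1. The log2 difference between flower and leaf was -5.31, and -4.36 without leaf41 and -5.97 without leaf1. With only the most abundant member of each family it was -7.02, and -10.05 between flower and root in place of -7.60, and leaf23 (7.28) and leaf41 (7.33) then lay above root33 (6.06).

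**Figure D4:**
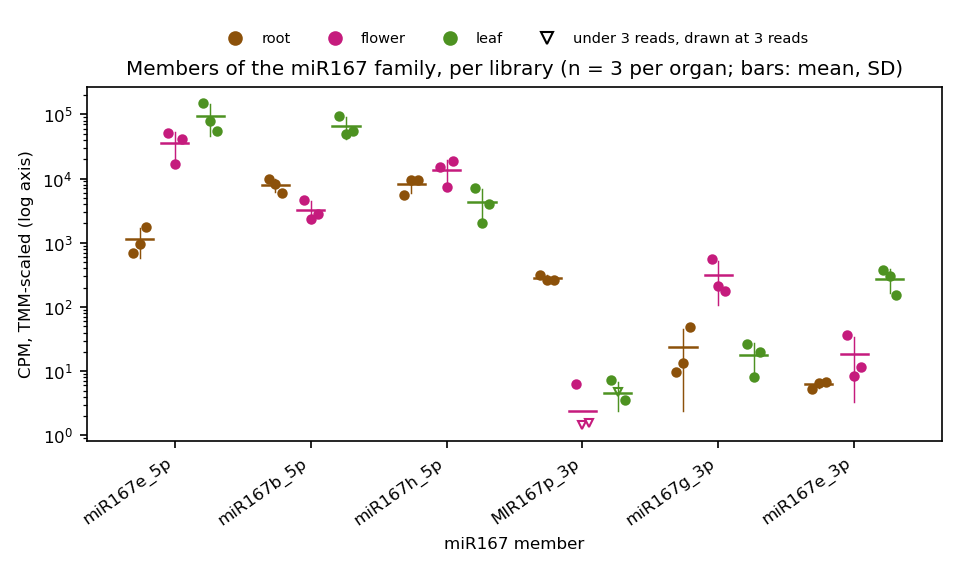
CPM after TMM scaling on a log axis for 6 members of the miR167 family in the 9 libraries, drawn as in the plot of 10 miRNAs. miR167b_5p, miR167e_3p and miR167e_5p are highest in leaf, the last not with the authors' divisor (log2 0.25, flower over leaf), miR167h_5p and miR167g_3p in flower, and MIR167p_3p in root.

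As checks on foreign or broken RNA, no row of the table belonged to the animal-numbered families, the questioned families or the names with no family number, so their share was 0% in all 9 libraries. This says what the authors' table lists and not what the libraries contained.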

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

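The authors' divisor as library size, each sequence under a single family, and lists without rows of 2 family names were alternatives chosen after the data were seen. Of the results that answer a comparison, 211 values under the alternatives counted as unchanged and 20 moved. Counts, those of lists included, had to stay within 1.5 times the reported count. The ratio and the share of the leading family had only to keep their sign, whatever the size of the shift. For the named miRNAs, the families and the counts of rows high or low in 1 organ, 4328 values were unchanged. For a miRNA or family this includes those called in neither setting, whatever their sign. A fold of at least 2 could change no call, as every call already met it. The number of unchanged values is therefore no measure of how stable the calls were. Among the miRNAs and families, 246 lost the call, 152 gained it and 5 reversed. Of the counts of rows, 33 moved beyond 1.5 times. DESeq2 called 85 miRNAs between root and leaf (50 with edgeR) and 17 families (10 with edgeR), and the cause was not tested.

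Leaving out 1 library in turn gave, between root and leaf, 29 miRNAs (without root23) to 86 (without leaf41) and 1 family (without root13) to 15 (without leaf41). Between flower and leaf it gave 5 families (without flower45) to 16 (without leaf41), and for organ-enriched miRNAs 28 (without root23) to 61 (without leaf41). The lists called ranged from 1 (without flower1 or leaf1) to 3 between flower and leaf, and from 0 (without root13 or flower2) to 1 between flower and root. Fewer libraries lower the power, and the cause of the higher counts was not tested here. With no low-count filter, camera called 1 list between root and leaf, silencing machinery (0 with it). An estimated correlation left 0 lists between flower and leaf and 0 between flower and root, and counting the same values once left 1 and 0.

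With the authors' divisor, the log2 fold change between flower and leaf turned to 0.25 for miR167e_5p, to 0.08 for miR171g_3p and to 0.19 for miR168a_5p and MIR168f_5p, which share a sequence. No other called miRNA changed sign under the 5 scalings. With each sequence under a single family, miR845 turned to -0.19 between root and leaf and -0.88 between flower and leaf, since nearly all its reads stand under other families too. The cause of the others was not tested. No paired analysis was possible because the numbers in the titles are shared by only flower1 with leaf1 and root23 with leaf23, fewer than 2 per pair of organs. Depth limits miRNAs near 3 counts per library, such as MIR167p_3p in flower and leaf.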

Other observations

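The tests of the leaf41 library, of members of a family that went opposite ways and of miR845 were chosen only after those results were seen, as was the comparison of the 2 arms of a precursor. Within families, the ratios of the members differed between root and leaf in 12 of 23 families, between flower and leaf in 10 and between flower and root in 13 (diffSpliceDGE in edgeR, adjusted p under 0.05). In the miR167 family, which targets auxin response factors, miR167b_5p stood at 65470 ± 23910 CPM in leaf and 3277 ± 1213 in flower (SD, n = 3 each), whereas miR167h_5p stood at 4338 ± 2525 in leaf and 13730 ± 5773 in flower. MIR167p_3p was found mostly in root, at 283 ± 30.4 CPM.

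The 5p and 3p arms were compared for 30 precursors, and their ratio differed among the organs for 12 (limma on log2 of the count plus 1). By the sign of the organ means alone, the leading arm differed for 3 of these. Whether a mean ratio differs from 0 in an organ was not tested. For miR396a, of a family that targets growth-regulating factors, the log2 ratio of 5p to 3p was 4.58 ± 0.84 in root, -0.32 ± 0.93 in flower and 4.32 ± 1.02 in leaf (SD, n = 3 each; limma adjusted p = 0.00123), but its 5p sequence is also listed as MIR396r_5p and its 3p sequence as MIR396g-3p, and the ratio for MIR396r was 0.83 ± 1.32 in flower. For miR171b it was 0.83 ± 0.33 in flower and -0.82 ± 2.59 in leaf, while in root the 5p arm had 0 or 1 counts per library and the 3p arm 3191 to 4166, so that no ratio is given there, and its 3p sequence is also listed as miR171m_3p. For MIR169k it was 2.82 ± 1.29 in root, -2.64 ± 1.82 in flower and 0.06 ± 3.10 in leaf (limma adjusted p = 0.034), from counts of 1 to 108 per arm and library.

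The leaf41 library had 19 sequences at least 4-fold above both other leaf libraries, among them miR394b_5p and miR156a_5p, where the other libraries had 0 to 3. Of the 19, 16 were also higher in root than in those 2 leaf libraries. At least 4-fold below both other libraries of the organ were 3 sequences in leaf41 (MIR408c_5p, MIR156j_3p and MIR7122a_3p). That count was 6 in leaf1, 5 in flower1 and 0 or 1 in the rest, so leaf41 stood out on the raised side only. Root RNA as the only source of the rise in leaf41 is argued against. Of the 19, 7 stood at least 2-fold above every root and other leaf library. An example was MIR398c_3p at 2099 RPTM with at most 12.95 in root. The flower means of these 7 ran from 0.31 RPTM (MIR156n_3p) to 8990 (MIR171z_5p), with 1780 for MIR398c_3p. Root RNA as a part of the rise stays open, as 16 of the 19 were also higher in root. A root library under a leaf name is argued against too, as 11 of 58 sequences abundant in root lay at least 4-fold below every root library (at most 1 for any root library), such as MIR171v_3p at 12.5 with at least 1100 in root. Both tests and their bounds were set after first versions left the matter undecided: the root share implied by 27 root-enriched sequences had a median of 32.9% and a maximum of 497%, and 40 of 80 sequences that separate the organs were nearer leaf. A difference in the age or state of the sampled leaves may remain, but the labels give none and no biological explanation was tested.

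Members of 7 families, 5p and 3p rows alike, were called in opposite directions in the same comparison with TMM. The choice among the 5 scalings moved the median log2 fold change by up to 1.65. It is argued against for the 6 families whose opposite calls held under all of them (miR156, miR166, miR167, miR171, miR172 and miR396). The miR396 case rested on 1 pair, between flower and root. Its higher member, miR403a_3p, shares its sequence with miR396h_3p, and its lower member was MIR396r_5p. That pair, and all miR166 pairs between flower and root, set opposite arms against each other (longest shared stretch 3 and 4 bases). The other families, and miR166 between flower and leaf, also had pairs of the same arm. Errors or trimming of a sibling at a rate common to all libraries would leave the ratios of the members unchanged. These ratios differed in the same comparison in the 6 families (diffSpliceDGE adjusted p of at most 0.00182). The families were picked for members called in opposite directions in that comparison, so this test could hardly end otherwise. It restates the selection, and no conclusion is drawn from it. Trimming that differs between organs stays open too: pairs that are no length variants of each other were found in 6 families, but either member can be a length variant of another sequence, listed or not. For the 4 of 91 pairs that are length variants, RPTM values were compared. The flower member exceeded the sum of both members in leaf in 3 (miR166h_3p, MIR172l_3p and MIR172l_5p). It did not for miR167h_5p, at 11300 RPTM in flower with 1150 and 17700 for both members in leaf. The authors' divisor places flower higher against leaf than TMM does, by 1.65 in the median log2 fold change. The sums were not compared under another scaling, so these pairs do not decide the question. A difference between the organs themselves stays open and was not tested.

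The miR845 total was higher in flower than in leaf by a log2 fold change of 2.28 ± 0.47 SE. Without the 3 rows whose sequence also stands under miR166 or miR171 it was -0.86 ± 0.69 (edgeR adjusted p = 0.384), which is consistent with reads shared with those rows as the source.

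Between 2 organs only 10 splits of the 6 libraries exist, too few for a share under 0.05. The real split between root and leaf gave 50 miRNAs, with at most 1 in another split, and 10 families, with at most 0, each the highest in 1 of 10 splits. Between flower and leaf it gave 68 miRNAs and 9 families, with at most 0 and 3 in another, and between flower and root 69 and 12, with at most 0 for both, again 1 of 10 splits each. For lists, the real values were 0, 2 and 1, the highest others 1, 2 and 2, and 10, 2 and 7 of the 10 splits gave as many. Among the 3 organs, 100 splits were drawn from 280. The real one gave 99 miRNAs by the F test, with at most 26 in another, and 44 organ-enriched rows, with at most 8. Each was matched by 1 of 100 splits, itself. A random grouping of these 9 libraries is thus argued against for both. The splits cannot judge chance differences between plants, as the labels do not say whether the libraries came from separate plants.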
